A study of Homo sapiens with 20 samples.

How the data were processed

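The series measured RNA of TK6, a human B lymphoblastoid cell line grown in suspension, on cDNA arrays read in 2 dyes. Each treated array set RNA of treated cells against RNA of wild type cells taken at 0 h. N-OH-AABP (N-hydroxy-4-acetylaminobiphenyl, an N-hydroxylated aromatic amide) was given at 0.5, 1 and 10 uM and labelled 27 h. BPDE (the anti diol epoxide of benzo[a]pyrene) was given at 17, 34 and 120 nM and labelled 1 h. These hours are called exposure times here, and the labels do not say when RNA was taken after exposure. Each of the 6 doses had 3 arrays, and 2 further arrays carried wild type RNA in both channels, which made 20 arrays. The labels gave treated RNA to Cy5 on array 1 of each dose and to Cy3 on array 2, the dye swap. On array 3 of each dose the labels gave Cy5 to both channels, so that its dye orientation was not settled. Array 3 was coded like array 1, by channel order, before the data were examined.

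The deposited values were log2 ratios of the 2 channels of each spot. That unit was read from the values, which ranged around 0 and had a ceiling of 16.6, the log2 of a fixed large ratio. The scanner, the background correction, the normalization and the centring were not given in the sources used here. The direction of the ratio was also not given, and Cy5 over Cy3 was taken as likely because the labels put Cy5 in channel 1. A ratio of Cy3 over Cy5 would turn the sign of every change reported here together, while the relative signs of genes, doses and compounds would stay. Medians of the deposited log2 ratio ran from -0.29 to 0.46 over the 20 arrays. The 38 values at the ceiling were treated as missing. No signal or background intensity came with the ratios, so the precision was limited by the number of arrays and the depth of each spot was unknown.

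The arrays held 17574 probes. The platform annotation gave 1 gene symbol to 9940 probes, several to 384 and none to 7250, which stay unnamed here. Symbols were updated through the gene identifier for 9909 of the probes with 1 symbol and kept as given for 31. Probes with the same single symbol were averaged, which gave 8061 named genes, of which 1529 had more than 1 probe. Each array was centred on its median. A feature needed a value on at least 2 arrays of every dose and at least 1 wild type array, and 15695 features were tested, with 0 left out by this filter.

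All 20 arrays entered 1 linear model in limma 3.58.1 under R 4.3.3, with a gene-wise dye term and each dose coded 1 or -1 by the channel that held the treated RNA. The wild type arrays carried the dye term alone. Adjusted p is Benjamini-Hochberg over all features of a comparison from limma's moderated test, with a threshold of 0.05. Where no feature changes, a share of 0.05 of the features tested is expected at an unadjusted p under 0.05. Counts of such features below that share are no sign of change. The comparisons were each dose against 0 h wild type, the mean of the 3 doses of each compound against wild type, N-OH-AABP minus BPDE, and the highest minus the lowest dose of each compound. The wild type RNA served as the reference on every array, so a ratio against 0 leaves out the spread between untreated cultures. The labels state duplicate cultures per condition, so at least 2 of the 3 arrays of a dose shared a culture, and which ones is not stated. The p-values may therefore be too small, since they measure a spread that is in part technical. No untreated array was taken at 1 h or 27 h, and compound, exposure time and dose unit change together.

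After the values were seen, the same model was fitted to the 14 arrays with stated dyes, without array 3 of each dose, and again to all 20 arrays with array 3 entered as a dye swap. These are called the stated-dye arrays and array 3 turned. The fit to the stated-dye arrays tested 15673 features with 7 residual degrees of freedom, and most genes named here come from it. Named genes were chosen by a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls by log2 change, or the first 3 each way for a single dose, among genes with 1 symbol that passed the threshold and had the same sign on every array compared. For a difference between groups the arrays of the groups were not to overlap, and where nothing passed the 4 smallest p were given as values. The sign on each array was taken after subtracting the fitted dye term. Members of the gene lists were named where they passed the test.

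The 25 gene lists were also fixed before the data were examined. They covered p53 targets, nucleotide excision repair, other DNA repair, DNA replication, mitosis, core histones, apoptosis, unfolded protein and amino acid stress, cytosolic heat shock, oxidative stress, xenobiotic metabolism, sterol synthesis, glycolysis and hypoxia, ribosomal proteins, ribosome biogenesis and MYC, oxidative phosphorylation, proteasome, interferon response, NF-kB and cytokines, immediate early genes and B cell identity. The remaining 4 held markers of other cell types: T and NK cells, myeloid cells, erythroid cells, and fibroblasts with epithelial cells. Some lists shared members, and the core histone list also held the linker histone H1-2. Each list with at least 5 measured genes was tested with cameraPR on the moderated statistic with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation.

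Alternatives set before the data were examined were no median centring, arrays scaled to one spread, no dye term, wild type arrays as a group, array weights, a robust variance, no filter, complete features alone, each probe on its own, arrays 1 and 2 averaged, the array number as a replicate block, an estimated correlation for the lists, and each array left out in turn. Alternatives added afterwards were both other treatments of array 3, a loess against the wild type arrays with a span of 0.3, and the dye swap of each dose averaged with the 3 doses as replicates of a compound. The model was tested on simulated data for N-OH-AABP minus BPDE with 200 changed features. With 15695 features and 20 arrays it recovered 30% of changes of 0.5 and 78% of changes of 1 on the log2 scale, with 7 false calls. With 15673 features and the 14 stated-dye arrays it recovered 11% and 69%, with 4 false calls. The simulated changes took array 3 as coded, and the noise was drawn independently for each array. The recovery with 20 arrays therefore does not hold if array 3 runs the other way. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.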

Results

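The experiment followed gene expression in TK6 cells after treatment with either of 2 DNA-damaging compounds, each at 3 concentrations. The series title names toxicity levels of 5%, 15% and 40%, and the labels used here do not assign them to doses. Both compounds form bulky DNA adducts, BPDE directly as a diol epoxide and N-OH-AABP through its N-hydroxy group. Each dose was measured on 3 arrays against 0 h wild type RNA, and 2 arrays compared wild type RNA with itself. Over all probes, the deposited log2 ratios of 190 array pairs correlated with a median r of 0.51 and a lowest of 0.0175. The arrays 2, with treated RNA in Cy3, correlated with the wild type self-comparisons at a median r of 0.665, close to the 0.672 between both self-comparisons. These are correlations across probes, which are not independent replicates.

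The direction of array 3 changed most results, so each comparison gives the count with all 20 arrays as coded, the count from the 14 stated-dye arrays, and the count with array 3 turned. Of 868 features that differed between the compounds on the stated-dye arrays, 3.34% had the same sign on array 3 as coded (29 features, exact 95% interval 2.25 to 4.76%). With array 3 turned the share was 96.7%, the remainder by construction. Both fits to 20 arrays hold the 14 stated-dye arrays, so calls shared between fits are not independent support. The 5 heat shock, chemokine and NF-kB genes CXCL10, NFKBIA, TRAF1, CD83 and HSPA8 each averaged between 1.59 and 3.44 above wild type under BPDE on the stated-dye arrays, on the log2 scale. On the 3 BPDE arrays numbered 3 they averaged -2.68, -1.49, -1.43, -1.48 and -1.39 as coded. All signs below take the ratio as Cy5 over Cy3, which the labels make likely without stating it, and all would turn together in the other case.

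**Figure D1:**
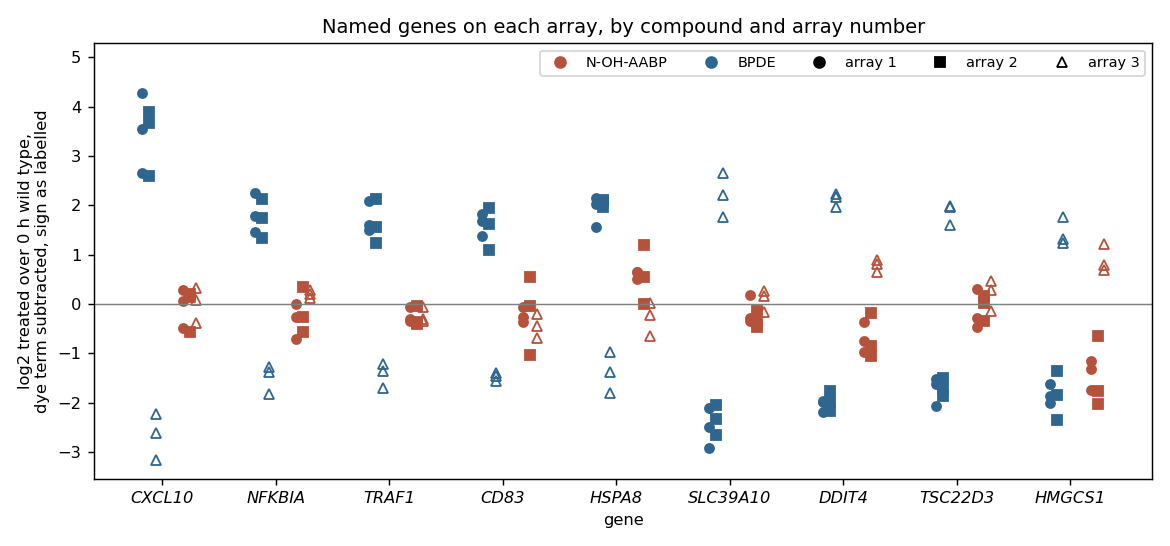
Log2 of treated over 0 h wild type on each array (vertical axis) for 9 genes (horizontal axis), set apart by compound and array number. The fitted dye term was subtracted. The sign follows the labels for arrays 1 and 2 and the channel order, as coded, for array 3. Circles are array 1, squares array 2 and open triangles array 3. For CXCL10 the BPDE arrays 1 and 2 average 3.44 and the BPDE arrays 3 average -2.68.

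Genes of NF-kB signalling and cytokines were lower after N-OH-AABP than after BPDE. CXCL10, a chemokine that attracts T cells, was lower after N-OH-AABP than after BPDE by a log2 difference of -3.50 (SE 0.209, adjusted p = 3.35e-05, 6 stated-dye arrays per compound). NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, differed by -2.03 (SE 0.127) and TRAF1, a signalling adaptor of TNF receptors, by -1.95 (SE 0.107). The lymphocyte surface proteins CD83 and CD40 differed by -1.80 (SE 0.165) and -1.39 (SE 0.119). In the other direction, SLC39A10, a zinc importer, was higher after N-OH-AABP than after BPDE by 2.19 (SE 0.124). TSC22D3, a glucocorticoid-induced leucine zipper protein, was higher by 1.62 (SE 0.122), and DDIT4, an inhibitor of mTORC1, by 1.32 (SE 0.15). The rule for named genes also gave others, none of them on the NF-kB list. Those lower after N-OH-AABP were MAN2A1 (-2.09), RGS1 (-1.95), PLEK (-1.53), HSPA8 (-1.39), UBD (-1.37), RAN (-1.37) and SLC5A6 (-1.36). Those higher were PRL (1.73), CDK19 (1.39), ERRFI1 (1.27), BNIP3L (1.24), RNF213 (1.22), PNRC1 (1.19), GLCCI1 (1.14), KYAT1 (1.14) and BOLA1 (1.13).

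Of the 19 measured genes of NF-kB and cytokines, 13 were lower after N-OH-AABP than after BPDE and 0 higher (16 and 0 adjusted over the list alone). The list had a median of -0.76 and an adjusted p of 7.5e-49, or an adjusted p of 1.24e-11 with an estimated correlation. BCL2A1, an anti-apoptotic protein, and RELB, an NF-kB subunit, were among its members at -1.25 and -0.67. In ribosome biogenesis and MYC, 9 of 19 genes were lower and 0 higher (12 and 1 adjusted over the list alone, adjusted p = 0.00199 with an estimated correlation). They included ODC1, the first enzyme of polyamine synthesis, at -1.25 and the nucleolar protein NOP56 at -1.14. Of 24 immediate early genes 8 were lower and 0 higher (8 and 0 adjusted over the list alone, adjusted p = 0.00199 with an estimated correlation), among them the transcription factor EGR3 at -1.03 and the phosphatase DUSP2 at -1.01. JUNB and IER3, also on the NF-kB list, and MYC, also on the ribosome biogenesis list, were among those lower, so these lists overlap. The median of the immediate early list was -0.21 with centred arrays and 0.06 without centring, which raised the median of all features in this comparison to 0.27, while the NF-kB and ribosome biogenesis lists stayed negative at -0.49 and -0.30.

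Several genes moved under both compounds without a difference between them that passed the test. HMGCS1, an enzyme of sterol synthesis, differed by 0.40 (95% interval -0.01 to 0.81, adjusted p = 0.291). The intervals were -0.73 to 0.14 for LDHA, -0.68 to 0.25 for ALDOA, -0.23 to 0.23 for PGK1, a glycolytic kinase, and -0.52 to 0.13 for NEB, a giant muscle filament protein. These genes were chosen after their values were seen, and an interval that holds 0 does not show that the compounds act alike.

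Other lists passed with the preset correlation and not with the estimated one, and without centring the medians of DNA replication, B cell identity and apoptosis turned positive, at 0.06, 0.19 and 0.17. Proteasome genes had 4 lower of 21 (8 adjusted over the list alone, adjusted p = 7.92e-07 and adjusted p = 0.176 with an estimated correlation). Unfolded protein and amino acid stress had 3 higher and 6 lower of 21 (3 and 9 adjusted over the list alone, adjusted p = 0.00159 and adjusted p = 0.322 with an estimated correlation). DNA replication had 3 lower of 23 (4 adjusted over the list alone, adjusted p = 0.00761 and adjusted p = 0.175 with an estimated correlation). B cell identity had 4 lower of 18 (4 adjusted over the list alone, adjusted p = 0.0186 and adjusted p = 0.322 with an estimated correlation). Mitosis had 4 higher of 28 (9 higher and 2 lower adjusted over the list alone, adjusted p = 0.0221 and adjusted p = 0.544 with an estimated correlation). Apoptosis had 3 lower of 20 (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.0316 and adjusted p = 0.209 with an estimated correlation). The markers of T and NK cells, myeloid cells, erythroid cells and fibroblasts with epithelial cells had adjusted p of 0.839, 0.826, 0.171 and 0.655.

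On the stated-dye arrays, 868 of 15673 features differed between the compounds, 326 higher and 542 lower after N-OH-AABP. With array 3 turned the number was 1477 (617 higher, 860 lower), and 809 features were called the same way in both, none in opposite directions. Array 3 was turned after its signs on the 868 features were seen, and both fits share the stated-dye arrays. Opposite calls were therefore unlikely from the start. With all 20 arrays as coded, limma called 0 of 15695 features. At an unadjusted p under 0.05 there were 442, below the share of 0.05 expected with no change. The smallest p there belonged to G3BP1, MPPED2, CNGA1 and BRINP1, at log2 differences of -0.52, -0.48, -0.48 and 0.95 and adjusted p of 0.996. In that fit the NF-kB list kept a median of -0.31 (adjusted p = 2.09e-05, adjusted p = 0.585 with an estimated correlation). Ribosomal proteins (median -0.12, adjusted p = 0.00143), ribosome biogenesis and MYC (-0.25, adjusted p = 0.000922), proteasome (-0.16, adjusted p = 6.7e-05) and DNA replication (-0.08, adjusted p = 0.0392) had the same adjusted p of 0.585 with an estimated correlation.

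The number of calls on the stated-dye arrays depended on the model: 6 without the dye term, 15 with the wild type arrays as a group, 205 with each dye swap averaged and doses as replicates, and 443 with the array number as a block, where the ribosome biogenesis list had an adjusted p of 0.0628 with an estimated correlation. Leaving out 1 array gave 409 to 1201. Without median centring it was 1959 (1782 higher, 177 lower), and the compounds differed in exposure time and dose as well as in structure.

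After 1 h of BPDE, chemokine and NF-kB genes and a group of chaperones were higher than in 0 h wild type cells. CXCL10 stood at 3.44 (SE 0.148, adjusted p = 1.24e-06), a 10.8-fold change, with an SD of 0.679 over 6 arrays and all 6 above 0. CCL3, another chemokine, was at 1.74 (SE 0.116), NFKBIA at 1.78 (SE 0.0896) and TRAF1 at 1.68 (SE 0.0758). HSPA8, the constitutive cytosolic HSP70, rose by 1.98 (SE 0.122) and DNAJA1, an HSP40 partner of HSP70, by 1.63 (SE 0.103). BNIP3L, a mitophagy receptor induced in hypoxia, fell by 2.45 (SE 0.128), SLC39A10 by a log2 change of -2.42 (SE 0.0877) and DDIT4 by one of -2.01 (SE 0.106).

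Of 2041 genes with a symbol that passed with the same sign on every array, the others among the 12 largest rises were MAN2A1 (1.81), NEB (1.72), CD83 (1.59), PLEK (1.36), ARPC2 (1.35) and IL18R1 (1.34). The others among the 12 largest falls were LUC7L3 (-2.29), SCD (-1.88, probes at -2.43 and -1.34), HMGCS1 (-1.85), PLD1 (-1.81), KCNN3 (-1.80), GSR (-1.74), TSC22D3 (-1.72), CD22 (-1.70) and RNF213 (-1.64). NF-kB and cytokines had 14 higher and 1 lower of 19 (14 and 1 adjusted over the list alone, median 0.78, adjusted p = 8.38e-08 with an estimated correlation), with JUNB at 1.14 and the subunits REL at 0.97 and NFKB1 at 0.77. Of 24 immediate early genes 10 rose and 0 fell (11 and 2 adjusted over the list alone, adjusted p = 0.00352 with an estimated correlation), including DUSP5 at 1.05. Of 9 cytosolic heat shock genes 5 rose and 0 fell (5 and 0 adjusted over the list alone, adjusted p = 0.00237 with an estimated correlation). DNAJB1, in that list at 0.49, had 2 probes that disagreed, at -0.10 and 1.08.

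Lipid and glycolytic genes moved the other way. Of 17 genes of sterol synthesis 10 fell and 1 rose (10 and 2 adjusted over the list alone, median -0.37, adjusted p = 1.81e-05 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, was at -1.85 (SE 0.130), and INSIG1, a sterol-sensing regulator, at -1.39. Of 16 genes of glycolysis and hypoxia 10 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.48, adjusted p = 0.00116 with an estimated correlation), with the glycolytic enzymes ALDOA at -0.88 and LDHA at -0.84.

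p53 targets had 7 lower and 1 higher of 19 (7 and 1 adjusted over the list alone, adjusted p = 0.0265, adjusted p = 0.298 with an estimated correlation). CCNG1, a cyclin G, was at -0.81, DDB2, a sensor of helix-distorting DNA damage, at -0.76, MDM2, the ubiquitin ligase of p53, at -0.45, and the death receptor FAS at 0.65. Ribosome biogenesis and MYC had 9 higher and 5 lower of 19 (9 and 6 adjusted over the list alone, adjusted p = 0.0202, adjusted p = 0.609 with an estimated correlation). Nucleotide excision repair had 3 higher and 4 lower of 19 (5 and 5 adjusted over the list alone, adjusted p = 0.32), with the damage-binding protein XPA at 0.52 and CCNH, a subunit of the kinase of TFIIH, at -0.80. Markers of T and NK cells, myeloid cells, erythroid cells and fibroblasts with epithelial cells had adjusted p of 0.547, 0.737, 0.508 and 0.974.

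In total 3912 features of the stated-dye arrays differed from wild type under BPDE, 2191 higher and 1721 lower, and with array 3 turned 4002 (2116 higher, 1886 lower), of which 3064 were shared. Leaving out 1 array gave 1961 to 4214 on the stated-dye arrays. The as-coded fit gave 1 to 300 features with 1 array left out, and 40 higher and 139 lower without centring. With all 20 arrays and centring it gave 43 features, 25 higher and 18 lower, all of them also called on the stated-dye arrays. In that fit cameraPR called 0 of 25 lists for BPDE, with 6 at an unadjusted p under 0.05 (1 with an estimated correlation), and the NF-kB list had a median of 0.40 (adjusted p = 0.0613, adjusted p = 0.877 with an estimated correlation). Of the 18 called genes with a symbol, 15 had the same sign on every array, and those that rose were EIF5 (0.92), POPDC2 (0.76), MPEG1 (0.66), RAC3 (0.60), FHDC1 (0.57) and MDM1 (0.49). Those that fell were ENG (-0.95), FKBP8 (-0.89), PRRC1 (-0.79), PHYHIPL (-0.76), TSPAN12 (-0.67), GRAMD1A (-0.64), MINK1 (-0.63), TEX56P (-0.60) and VCPKMT (-0.54). The rule required the same sign on every array with array 3 as coded. Only 3.34% of the 868 features that differed between the compounds kept their stated-dye sign in that direction. Whether these genes follow BPDE or the dye profile was not tested. Arrays 1 and 2 may differ in dye profile, which a comparison with wild type would carry. Over features, the BPDE change correlated with the dye term at r -0.321 on the stated-dye arrays. The r was -0.502 as coded and -0.149 with array 3 turned. The stated-dye number fell to 460 without the dye term, to 5 with the wild type arrays as a group and to 2119 (1618 higher, 501 lower) with the array number as a block, which ties the unswapped wild type array 2 to the swapped arrays and in which the NF-kB, sterol, glycolysis, heat shock and immediate early lists had adjusted p of 0.258, 0.107, 0.0594, 0.352 and 0.352 with an estimated correlation.

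After 27 h of N-OH-AABP, genes of glycolysis, sterol synthesis and ribosome biogenesis were lower than in 0 h wild type cells, though the sterol median turned positive without centring. HMGCS1 fell by 1.45 (SE 0.130, adjusted p = 0.00118, lower on 6 of 6 arrays). LDHA, which turns pyruvate into lactate, was at -1.13 (SE 0.139) and ALDOA, the glycolytic aldolase, at -1.10 (SE 0.148). MT1X, a metal-binding metallothionein, was at -1.03 (SE 0.100). In the other direction DNAJB1, an HSP40 chaperone, rose by 1.37 (SE 0.124, with its 2 probes apart at 0.94 and 1.80) and PRL, the hormone prolactin, by 1.55 (SE 0.229).

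Of 623 genes with a symbol that passed with the same sign on every array, the others among the 12 largest rises were CA3 (1.54), NEB (1.52), APOC2 (1.18), PDGFRL (1.18), RCAN3 (0.98), EFNB3 (0.96), ECSCR (0.94), LOC729291 (0.92), CD9 (0.90) and TSC1 (0.86). The others among the 12 largest falls were SCD (-1.37, probes at -1.73 and -1.01), LDHC (-1.34), BNIP3L (-1.21), DTL (-1.07), CNBP (-1.06), CD22 (-1.05), CS (-0.99) and RGS1 (-0.95). Of 16 genes of glycolysis and hypoxia 9 fell and 0 rose (10 and 0 adjusted over the list alone, median -0.41, or -0.14 without centring, adjusted p = 5.18e-06 with an estimated correlation). In ribosome biogenesis and MYC 11 of 19 fell and 0 rose (15 and 1 adjusted over the list alone, median -0.34, or -0.07 without centring, adjusted p = 0.0111 with an estimated correlation), including NCL at -0.62 and MYC at -0.46. Of 9 cytosolic heat shock genes 5 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.30, adjusted p = 0.0062 with an estimated correlation), with DNAJA1 at 0.72 and HSPA8 at 0.59.

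Centring decided the sign of other lists. Sterol synthesis had 6 lower and 0 higher of 17 (8 and 0 adjusted over the list alone, adjusted p = 5.18e-06 with an estimated correlation), with a median of -0.22 that became 0.05 without centring. DNA replication had 4 lower and 0 higher of 23 (9 and 0 adjusted over the list alone, adjusted p = 0.0119 with an estimated correlation), with the replicative helicase subunit MCM5 at -0.56 and the sliding clamp PCNA at -0.43, and its median of -0.21 became 0.06. Oxidative stress had 6 lower and 0 higher of 17 (7 and 0 adjusted over the list alone, adjusted p = 0.00284 with an estimated correlation), with a median of -0.03 that became 0.25. Its members that fell were the metallothioneins MT1X, MT1E (-0.72) and MT1G (-0.58), the pentose phosphate enzymes PGD (-0.69) and TKT (-0.37), and the peroxidase PRDX1 (-0.33). Leaving out the centring raised the median of all features under N-OH-AABP to 0.29, and these lists stayed below that median.

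The next 4 lists had negative medians that became 0.10, 0.05, 0.14 and 0.17 without centring. Proteasome had 5 lower of 21 (8 adjusted over the list alone, adjusted p = 9.5e-05, adjusted p = 0.286 with an estimated correlation). B cell identity had 6 lower and 1 higher of 18 (9 and 1 adjusted over the list alone, adjusted p = 9.66e-05, adjusted p = 0.136 with an estimated correlation), with CD22, an inhibitory B cell receptor, at -1.05 and the transcription factor IRF4 at -0.71. For ribosomal proteins limma called 0 of 24 (0 adjusted over the list alone, 5 at an unadjusted p under 0.05, median -0.13, adjusted p = 0.00936, adjusted p = 0.506 with an estimated correlation). Oxidative phosphorylation had 2 lower of 28 (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.0497, adjusted p = 0.548 with an estimated correlation). p53 targets had 3 higher and 2 lower of 19 (3 and 2 adjusted over the list alone, adjusted p = 0.355), with RPS27L at 0.57, the p53-inducible reductase subunit RRM2B at 0.36 and the damage recognition protein XPC at 0.33. Markers of T and NK cells, myeloid cells, erythroid cells and fibroblasts with epithelial cells had adjusted p of 0.421, 0.722, 0.645 and 0.5.

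In total 1210 features of the stated-dye arrays differed from wild type under N-OH-AABP, 577 higher and 633 lower, and with array 3 turned 1355 (601 higher, 754 lower), of which 778 were shared. The stated-dye number was 1506 with the array number as a block (1287 higher, 219 lower) and fell to 99 without array 1 at 1 uM. As coded, the 20 arrays gave 141 features (0 to 189 with 1 array left out), 120 higher and 21 lower (991 and 14 without centring). Of the 141, 98 were shared with the stated-dye arrays. Of the 68 called genes with a symbol, 52 had the same sign on every array, and among these the 12 that rose most were PRL (1.11), RCAN3 (0.89), RGN (0.82), ALDH3B2 (0.81), TM4SF1 (0.77), SPATC1L (0.74), GATA6 (0.73), PTPRM (0.71), TBC1D8B (0.69), HHAT (0.66), IYD (0.65) and PROZ (0.65). The 9 among them that fell were FKBP8 (-0.87), ENG (-0.85), TSPAN12 (-0.67), CPSF7 (-0.62), SF3A1 (-0.62), PHYHIPL (-0.56), PSAP (-0.47), TNFRSF8 (-0.37) and RPS6KB2 (-0.36). As for BPDE, this choice took array 3 as coded. Whether these genes follow N-OH-AABP or the dye profile was not tested. In that fit glycolysis and sterol synthesis had adjusted p of 0.0229 each, and DNA replication and ribosome biogenesis 0.036 each, all with an adjusted p of 0.652 with an estimated correlation. Over features the change correlated with the dye term at r -0.424 on the stated-dye arrays, -0.611 as coded and -0.113 with array 3 turned. On the stated-dye arrays limma called 0 without the dye term and 0 with the wild type arrays as a group. At an unadjusted p under 0.05 these had 958 and 1000. It called 218 with each dye swap averaged, and 6989 (6838 higher, 151 lower) without centring. With the array number as a block, the glycolysis, oxidative stress, sterol, ribosome biogenesis, DNA replication and heat shock lists had adjusted p of 0.044, 0.044, 0.149, 0.212, 0.149 and 0.656 with an estimated correlation.

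**Figure D2:**
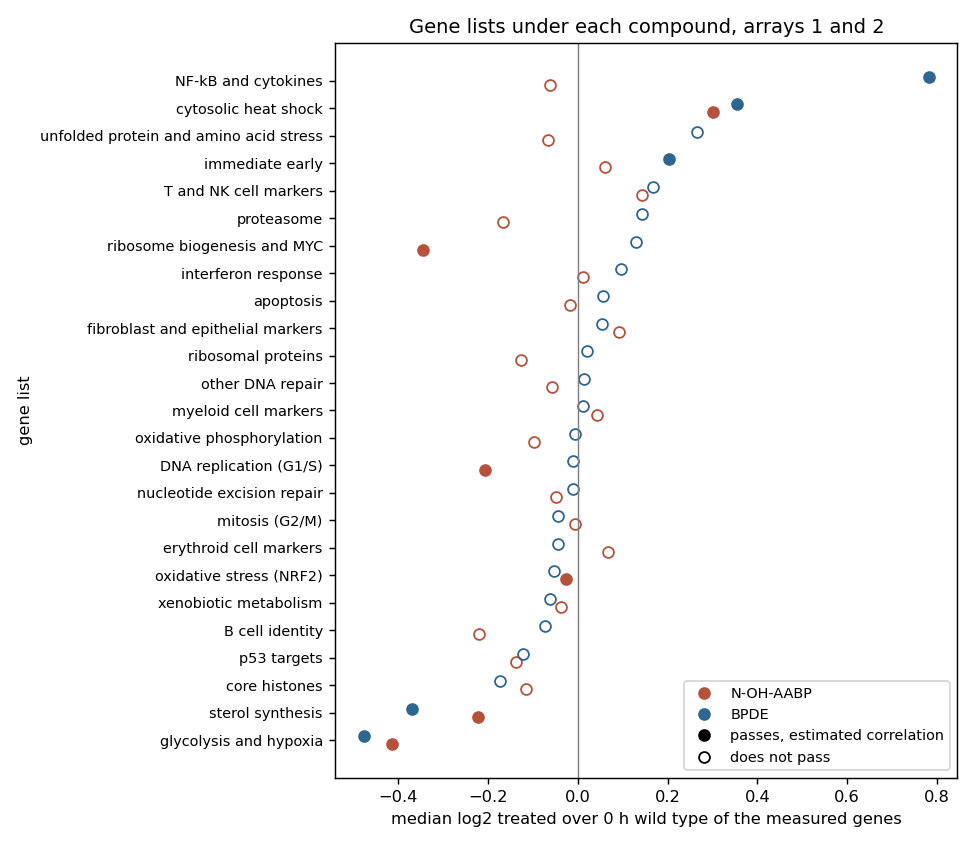
Median log2 change against 0 h wild type of each gene list (horizontal axis, log2 units) for BPDE and N-OH-AABP on arrays 1 and 2. Filled points pass the threshold with an estimated correlation. The NF-kB and cytokines list lies at 0.78 for BPDE and -0.06 for N-OH-AABP (0.21 without centring), and glycolysis and hypoxia at -0.48 and -0.41.

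The sterol, glycolysis and heat shock lists shifted the same way under both compounds, except that the sterol median after N-OH-AABP was 0.05 without centring. Not every member did: SREBF1 was at 0.25 after BPDE and -0.11 after N-OH-AABP, and VEGFA at 0.33 and -0.07. With the array number as a block and an estimated correlation, only the glycolysis list after N-OH-AABP passed among these lists. HMGCS1 was at -1.85 after BPDE and -1.45 after N-OH-AABP, BNIP3L at -2.45 and -1.21, and NEB at 1.72 and 1.52. In all, 280 features of the stated-dye arrays were higher under both compounds and 345 lower under both, where independent lists of the same sizes would share 80.7 and 69.5. Over all features the changes correlated at r 0.498, against 0.00194 in simulated unchanged groups with the same design. The simulation held array noise alone. Variation of the 0 h reference RNA and dye profiles that differ between sets were not simulated. The covariance was 0.0409, and the difference from the simulated covariance was also 0.0409. As coded, the 20 arrays shared 8 higher and 7 lower features, against 0.191 and 0.0241 for independent lists. Part of the excess may come from the wild type reference and the dye profiles that both comparisons share.

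CXCL10 and BNIP3L were among the leading genes at each BPDE dose. CXCL10 stood at 3.17, 4.08 and 3.06 after 17, 34 and 120 nM (SE 0.256 each, 2 stated-dye arrays per dose). BNIP3L was at -2.24, -2.75 and -2.35. The other leading genes were CCL3 (1.91), LYPD6 (1.85), LUC7L3 (-2.56) and SLC39A10 (-2.41) at 17 nM, and NFKBIA (2.18), TRAF1 (2.11), SLC39A10 (-2.78) and LUC7L3 (-2.15) at 34 nM. At 120 nM they were HSPA8 (2.05), OTP (1.93), SCD (-2.31) and GSR (-2.22). The stated-dye arrays gave 992, 782 and 817 features at 17, 34 and 120 nM, and array 3 turned gave 1188, 1465 and 1214. With the array number as a block the stated-dye arrays gave 1008, 391 and 527, and with the loess 1012, 1039 and 1095. As coded, the 20 arrays gave 13 at 17 nM, all higher, with MPEG1 (1.26), COL3A1 (1.18) and CNGA1 (0.89) leading. This count was 0 without centring, 0 with arrays scaled to one spread and 0 to 19 with 1 array left out. At 34 and 120 nM limma called 0 and 0 as coded, with 411 and 1361 features at an unadjusted p under 0.05. TSPAN12 had the smallest p at both, at -0.74 and -0.81.

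After 0.5 uM N-OH-AABP, NEB (1.80), AKAP6 (1.49) and KANK1 (1.41) rose most and HMGCS1 (-1.89), LDHA (-1.81) and LDHC (-1.74) fell most on the stated-dye arrays. At 10 uM the named genes that passed were NEB (1.43) and SAT1 (-1.01), a catabolic enzyme of polyamines. At 1 uM 1 unnamed feature passed, and the smallest p among named genes belonged to DNAJB1 (1.61), NEB (1.34), UBD (-0.84) and SAT1 (-0.73). The stated-dye arrays gave 299, 1 and 4 features at 0.5, 1 and 10 uM, and array 3 turned gave 787, 55 and 89. With the array number as a block the stated-dye arrays gave 1348, 334 and 229, and with the loess 110, 5 and 12. As coded limma called 0 at each dose, with 2133, 601 and 931 features at an unadjusted p under 0.05, and the smallest p belonged to PDS5A (-1.14), ALDH3B2 (1.03) and TSPAN12 (-0.74). A difference in the number of calls between doses is not a test of the doses against each other. Array 2 at 0.5 uM had the widest spread of log2 ratios of all arrays (scaled median absolute deviation 0.928, next 0.697). Over features, the changes at 0.5, 1 and 10 uM correlated with the dye term at r -0.627, -0.085 and -0.118 on the stated-dye arrays. Whether these explain the higher count at 0.5 uM was not tested.

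The highest and lowest doses were compared directly to ask for a dose response. No gene passed for either compound. For N-OH-AABP at 10 minus 0.5 uM the smallest p on the stated-dye arrays belonged to KIF21B (-1.01), MFGE8 (0.99), PCDH9 (-4.62) and the metallothionein MT1E (1.33), each with an adjusted p of 0.236. For BPDE at 120 minus 17 nM it belonged to NBAT1 (-1.59), FAP (-2.73), CNGA1 (-1.21) and AKR1C3 (-0.90), each with an adjusted p of 1. limma called 0 features in both comparisons in all 3 treatments of array 3. For N-OH-AABP the unadjusted p was under 0.05 for 425 features as coded, 1992 on the stated-dye arrays and 1626 with array 3 turned, and for BPDE for 597, 591 and 376. As coded the smallest p belonged to GJB5 (-1.37), GORAB (-0.63), TPPP (0.96) and EXTL3 (-0.57) for N-OH-AABP, and to COL3A1 (-1.43), CD209 (-1.18), F2RL2 (-1.29) and MPP3 (-0.98) for BPDE. In simulated data the fit to the stated-dye arrays recovered 28% and 30% of dose differences of 1 on the log2 scale for N-OH-AABP and BPDE, and 87% and 93% of differences of 2, so these counts do not show that the doses acted alike.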

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

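All tests in this part, the counts of other splits of the arrays included, had their bounds written after the results were seen.

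RGS1, a regulator of G protein signalling in B cells, led a set of 64 features that were higher than wild type under 1 compound and lower under the other on the stated-dye arrays, and this difference between the groups is what singled them out. RGS1 was at -0.95 after N-OH-AABP and 1.00 after BPDE. The ubiquitin-like protein UBD was at -0.63 and 0.75, the nuclear transport GTPase RAN at -0.48 and 0.89, and the death receptor FAS at -0.37 and 0.65. RRM2B went the other way, at 0.36 and -0.33. All 64 were also called in N-OH-AABP minus BPDE, which their opposite calls in the same fit made nearly certain, so this adds no support. Without centring, 62 of the 64 kept opposite signs, 22 passed under both compounds and 56 passed between the compounds. After N-OH-AABP, RAN was then at -0.21 (adjusted p = 0.0718) and FAS at -0.10 (adjusted p = 0.293), so neither passed as lower than wild type.

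The arrays numbered 3 ran against the arrays numbered 1. Treated RNA in Cy5 would give most compound differences the same sign on both, and 3.34% of 868 features had it; exchanged compound names would leave the sign of the mean over both compounds in place, and 23.7% of the 868 kept it (206, exact 95% interval 20.9 to 26.7%). A dye bias of that set alone would cancel in its compound difference, which instead correlated with that of the other arrays at r -0.349. Treated RNA in Cy3 may be the orientation, and it stays open because 4 of the 6 arrays correlated below 0 with their own dose when set against their set's mean, at -0.238, -0.250, -0.199 and -0.166 against 0.0258 and 0.00624. Before any sign was turned, the compound difference was also taken at each of the 3 pairings of doses. There array 3 correlated with array 1 at r -0.217, -0.230 and -0.197, and with array 2 at 0.133, 0.164 and 0.135. Treated RNA in Cy3 would give these signs. No biological explanation was tested.

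HMGCS1, BNIP3L and NEB stood for 625 features that changed the same way under both compounds. A response shared by the treated cultures stays open: 77.3% of the 625 (483) had that sign on array 3 turned, against 49.9% in simulated unchanged groups, and a dye bias common to sets 2 and 3 or the 0 h wild type RNA common to all arrays could raise that share too. Dye bias that differs between sets of arrays also stays open, since sets 2 and 3 differed by 0.917 times the spread between sets 1 and 2. The data hold no untreated culture at 1 h or 27 h, so a change with time in culture also stays open and was not tested.

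CXCL10, NFKBIA, TRAF1 and CD83 were higher after BPDE than after N-OH-AABP. A dye bias common to the arrays of a set would cancel in the compound difference within the set and leave it near 0, and the NF-kB list median of N-OH-AABP minus BPDE instead lay below 0 in 2 of 2 sets with stated dyes, at -0.93 (9 pairs of doses, -1.17 to -0.54) and -0.71 (-1.17 to -0.42), while set 3, whose sign depends on its direction, had 0.65 as coded. Exposure time cannot be told apart from compound, since 0 arrays of a compound were taken at the time of the other. A reversed ratio, which would make these genes lower after BPDE, stays open because 0 labels name its direction. A difference between the compounds themselves is among the open explanations.

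Other splits of the arrays were counted for the compound difference with the doses of each group pooled. On the stated-dye arrays the real split called 1036 features, 1 of 100 splits gave as many (the real one), and the highest of the others was 1. Among splits that kept each set balanced the count was also 1 of 100, with 11 as the highest of the others, so chance was excluded for splits that treat single arrays as independent. Arrays of a dose may share a culture, and the 10 splits of the 6 whole doses are too few for a share under 0.05: the real one called 1036 and the highest other 0. As coded, the real split called 0, which each of the 100 of 100 splits reaches by construction (the highest other was 5), so nothing about chance follows there. For the highest minus the lowest dose of each compound the 10 splits are too few for a share under 0.05. The real value was 0, the highest other was 0, and 10 of 10 splits were as large.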

How the results depend on the processing

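All settings that change array 3, the loess and the averaging of dye swaps with doses as replicates were chosen after seeing the data; the others were planned. With all 20 arrays as coded, the counts of changed features were 141 for N-OH-AABP, 43 for BPDE, 0 for their difference and 13 for BPDE at 17 nM. Leaving out median centring gave 1005, 179 and 1, with 22 for N-OH-AABP at 0.5 uM and 0 for BPDE at 17 nM (2705 at an unadjusted p under 0.05). Scaling arrays to one spread gave 0 for N-OH-AABP, 5 for BPDE (all lower) and 0 at 17 nM, with 1714 and 904 at an unadjusted p under 0.05 where it gave 0. Leaving out the dye term, taking the wild type arrays as a group, and averaging arrays 1 and 2 each gave 0 for N-OH-AABP, 0 for BPDE and 0 at 17 nM. At an unadjusted p under 0.05, limma then had 405, 708 and 2015 features for N-OH-AABP, 1081, 589 and 1849 for BPDE and 136, 530 and 1363 at 17 nM. Array weights gave 921 for N-OH-AABP and 4279 for BPDE, with 32 at 1 uM and 442, 799 and 32 at 17, 34 and 120 nM. The replicate block gave 2606 and 2305, with 1948, 1183 and 920 at 0.5, 1 and 10 uM and 2221, 540 and 577 at 17, 34 and 120 nM. The stated-dye arrays gave 1210, 3912 and 868, with 299, 1 and 4 at 0.5, 1 and 10 uM and 992, 782 and 817 at 17, 34 and 120 nM. Array 3 turned gave 1355, 4002 and 1477, with 787, 55 and 89 and then 1188, 1465 and 1214. Shifted lists over the 3 comparisons numbered 9 as coded, 0 with an estimated correlation, 3 with scaled arrays, 26 with the replicate block, 26 on the stated-dye arrays and 28 with array 3 turned. Features changed the same way under both compounds numbered 15 as coded, 40 without centring, 0 with scaled arrays, 0 without the dye term, 1964 with the replicate block, 625 on the stated-dye arrays and 736 with array 3 turned. On the stated-dye arrays, leaving out centring gave 6989 for N-OH-AABP and 1959 for the difference. Leaving out the dye term gave 0, 460 and 6, and the wild type arrays as a group 0, 5 and 15. Array weights gave 444 for N-OH-AABP. The replicate block gave 2119 for BPDE and 443 for the difference, of which 431 were among the 868. Averaged dye swaps with doses as replicates gave 218 and 205, 182 of them among the 868, with 4 residual degrees of freedom. Array 3 turned with the replicate block gave 3238 and 1534. The loess gave 1043, 3981 and 1029. By construction the averaged fits have fewer degrees of freedom, and the fits without a dye term or with wild type as a group leave the dye difference of arrays 1 and 2 in the spread; otherwise the cause was not tested. The array numbers were not taken to pair the samples, since some arrays with the same number deviated in opposite ways, and the values still hint at a deviation shared within some numbers. As coded, 45 pairs with the same number had deviations correlating at a median r of 0.216, from -0.447 to 0.574, against -0.0166 for 90 other pairs, and 11 of 18 arrays correlated best with their own number. With array 3 turned the medians were 0.187 and -0.0579, and 12 of 18 did. On the stated-dye arrays, where both arrays of a dose mirror each other by construction, the medians were -0.185 and 0.185, and 0 of 12 did.

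Leaving out 1 array at a time as coded gave 0 to 189 for N-OH-AABP, 1 to 300 for BPDE, 0 to 19 at 17 nM, 0 to 0 at 34 nM, 0 to 3 at 120 nM, 0 to 24 at 0.5 uM, and 0 to 0 at 1 uM and at 10 uM. The difference between the compounds and N-OH-AABP at 10 minus 0.5 uM stayed at 0, and BPDE at 120 minus 17 nM ran from 0 to 3. On the stated-dye arrays N-OH-AABP ran from 99 to 1391 and moved by over 1.5 times without array 1 at 1 uM (99) or 10 uM (703), array 2 at 0.5, 1 or 10 uM (470, 309 and 302) or wild type array 2 (760). BPDE ran from 1961 to 4214 and moved without array 1 at 34 nM (1961) or array 2 at 17 or 120 nM (2137 and 2451). The difference ran from 409 to 1201 and moved without array 1 at 1 or 10 uM (409 and 525) or at 34 or 120 nM (486 and 503), and without array 2 at 1 uM (454) or at 17 or 34 nM (484 and 525). Where this left 1 array of a dose, it was taken to vary like the others. Of 72 values of named genes on the stated-dye arrays none reversed, and the threshold was lost by 69 as coded with array 3, 46 without the dye term, 10 with the replicate block, 8 with array 3 turned, 6 with array weights, 5 with scaled arrays and 0 without centring. These genes were chosen for large changes on the stated-dye arrays, and each setting uses those arrays again. A reversal was therefore unlikely from the start, and its absence adds no support. No signal over background came with the ratios, so its effect was not examined.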

Other observations

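The list counts in this part come from lists fixed before the data were examined, and the choice of which members to describe was made after their values were seen.

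All values in this part come from the stated-dye arrays. After BPDE the mitotic genes HMMR (-0.79), TPX2 (-0.76), BUB1B (-0.72) and BUB1 (-0.72), which act at the spindle, were lower, while KIF23 (0.69), UBE2C (0.55) and MKI67 (0.48) were higher. The mitosis list had 4 higher and 7 lower of 28 (4 and 8 adjusted over the list alone, adjusted p = 0.128). After N-OH-AABP it had 3 higher and 1 lower (4 and 3 adjusted over the list alone, adjusted p = 0.581). DNA replication after BPDE had 4 higher and 1 lower of 23 (4 and 2 adjusted over the list alone, adjusted p = 0.974), with MCM3 at 0.59. The core histone list had 2 higher and 3 lower of 7 after BPDE (2 and 3 adjusted over the list alone, adjusted p = 0.751), with H2AX at 0.83 and H2BC12 at -0.71. The linker histone H1-2, also on that list, was among those lower, at -0.44. After N-OH-AABP the list had 2 lower (2 adjusted over the list alone, adjusted p = 0.148). Other DNA repair had 3 higher and 2 lower of 25 after BPDE (1 and 2 adjusted over the list alone, adjusted p = 0.949) and 3 lower after N-OH-AABP (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.103), with the flap endonuclease FEN1 at 0.24 and -0.50. Nucleotide excision repair after N-OH-AABP had 1 higher and 1 lower of 19 (1 and 1 adjusted over the list alone, adjusted p = 0.112).

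Interferon response genes had 5 higher and 2 lower of 20 after BPDE (6 and 2 adjusted over the list alone, adjusted p = 0.547) and 4 higher and 1 lower after N-OH-AABP (4 and 2 adjusted over the list alone, adjusted p = 0.421). IFIT1, an antiviral RNA-binding protein, was at 0.86 after N-OH-AABP, and ISG20, an exonuclease, at 0.83 after BPDE. Unfolded protein and amino acid stress after BPDE had 9 higher and 2 lower of 21 (12 and 3 adjusted over the list alone, adjusted p = 0.0657), with SARS1 at 0.88, PDIA4 at 0.79 and HSP90B1 at 0.72. Apoptosis had 6 higher and 1 lower of 20 after BPDE (7 and 1 adjusted over the list alone, adjusted p = 0.185), with BCL2A1 at 1.28. Proteasome had 6 higher of 21 after BPDE (8 adjusted over the list alone, adjusted p = 0.131). B cell identity had 5 higher and 7 lower of 18 after BPDE (5 and 8 adjusted over the list alone, adjusted p = 0.904), with the costimulatory protein CD86 at 0.94. Xenobiotic metabolism had 1 higher and 4 lower of 18 after BPDE (1 and 4 adjusted over the list alone, adjusted p = 0.547) and limma called 0 of 18 after N-OH-AABP (0 adjusted over the list alone, 4 at an unadjusted p under 0.05, adjusted p = 0.49), with the glutathione transferase GSTP1 at -0.41 after BPDE. Oxidative stress had 4 higher and 4 lower of 17 after BPDE (4 and 5 adjusted over the list alone, adjusted p = 0.623), with glutathione reductase, GSR, at -1.74.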
